A study of Arabidopsis thaliana with 28 samples.

How the data were processed

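The study collected Arabidopsis thaliana Col-0 seedlings after ABA or an ethanol mock at 0.5, 1, 3, 6, 9, 12 and 24 h, with 2 libraries for each of 14 groups, and sequenced their RNA with paired-end reads on Illumina instruments. Per the submitters' processing notes, the authors checked reads with FastQC and aligned them with STAR to the TAIR10 genome, with no versions given. The quantifier, the test, its threshold and the way the 2 libraries of a group were combined are not given in the sources used here, nor are the ABA dose and the age of the seedlings. Whether the 2 libraries came from separate cultures is not stated either.

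The deposited table holds 33557 entries, with 1 FPKM value per gene and group, made by the authors from the 2 libraries together. The FPKM unit of these deposited values was inferred from the values, since the file headers name none. Among genes with 1 annotated transcript, values were multiplied by the transcript length minus 250 bases. The most frequent low product in a pool was taken as a single fragment. Whether low values fell on whole multiples of it was not tested. This product, the step between low values, gave the implied fragments per pool. The deposited log2 column holds the authors' log2 of the ABA value over the mock value with no pseudocount, which was checked on the file (largest gap 0.00262, with a tolerance of 0.01). The deposited yes/no calls are the authors' own calls of significance at each time. In 8288 entries all pools were listed at 0. Names and transcript lengths were taken from the TAIR10.1 annotation, which matched 32813 entries, 26690 of them protein-coding.

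The analysis chosen before the data were examined was a limma fit of the 28 libraries, with the lists, the alternatives and the rule for named genes set at the same time. Since the table holds pools and not libraries, no test at a single time could be run, and the authors' calls stand for it. They were counted for all genes and for genes at least 2-fold apart. For the other questions limma 3.58.1 (R 4.3.3; eBayes with a trend, not robust) was fitted to log2(FPKM + 1), over 20034 genes with at least 1 FPKM in at least 2 pools. The pseudocount of 1 makes fold differences of genes near 0 FPKM smaller than their ratios. The averaged ABA effect is the mean of the 7 differences of ABA minus mock (6 residual degrees of freedom). The late minus early effect is the mean difference at 9, 12 and 24 h minus that at 0.5 and 1 h, in a fit of 3 phases (4 degrees of freedom). The effect by time and the mock time course are slopes on log2 hours (5 degrees of freedom), which took the place of planned tests for any difference between times. These fits were chosen after seeing that the values were pooled. Their error is the spread between times, which includes real change over time. The fits treat the 7 times as independent, which was not tested, so p-values may be too small where neighbouring times are alike. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05.

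The fits were tested on simulated data, in which 200 of 20034 genes were changed, 50 each by 0.5, 1, 2 or 4 on the log2 scale. The noise was 0.5 times each gene's spread over the mock pools, with that spread held to at most 1. It was independent between genes and times, and far fewer genes were changed than the 9417 that passed in the data. The recovered shares may therefore be too high for the real data. The share recovered was 78, 96, 100 and 100% for the averaged effect, 2, 46, 88 and 100% for late minus early, 2, 40, 86 and 100% for the effect by time and 20, 62, 100 and 100% for the mock time course.

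The 27 gene lists, fixed with the design and matched by locus, were ABA receptors, clade A PP2C phosphatases, SnRK2 kinases and ABF/ABI transcription factors, ABA biosynthesis, ABA catabolism, LEA with dehydrin and cold-regulated genes, osmolyte metabolism, ABA- and drought-related transcription factors, photosynthesis, chlorophyll breakdown and leaf senescence, circadian clock, cell cycle, cell wall loosening, aquaporins, auxin response, type-A cytokinin response regulators, gibberellin metabolism and receptors, jasmonate response, salicylate defence, small RNA machinery, microRNA targets, hypoxia response, touch and early stress, heat shock, root markers, guard cell markers, and seed storage and oil body. They were tested with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01 and with an estimated correlation. Limma's fry was also run; it asks whether a list's genes move one way on balance and does not compare them with other genes. P-values were adjusted over the 27 lists of a comparison.

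Genes were named by rule. At each time these were the 3 largest rises and falls among genes called by the authors with a mean of at least 5 FPKM. For the averaged effect they were the 10 largest in each direction with the same sign at 7 of 7 times, for late minus early the 5 largest in each direction, and for the slopes the 10 smallest p-values. Up to 4 members of each list with the largest effects, and 20 genes chosen in advance, were added. The planned condition that both libraries of a group agree in direction could not be applied. Genes named outside the rule as examples were chosen after their values were seen.

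Alternatives were pseudocounts of 0.1 and 5, quantile normalization, no filter on low values, a filter of at least 5 FPKM in at least 4 pools, a 2-fold threshold, the estimated correlation and fry. Chosen after seeing the data were the removal of the trend of the 24 h effect with transcript length (lowess), leaving out each time in turn, and the count of 2-fold differences whatever the call. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Not run, since the table holds no libraries and no counts, were replicate similarity, tests on counts, fits of the libraries of a single time or of the mock libraries alone, and leaving out single libraries. Raw reads were not analysed here.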

Results

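Gene expression was measured by paired-end RNA sequencing in seedlings of the Arabidopsis thaliana Col-0 wild type exposed to abscisic acid (ABA), the plant hormone of drought responses and seed dormancy, or to an ethanol mock. Seedlings were collected at 0.5, 1, 3, 6, 9, 12 and 24 h, with 2 libraries for each of the 14 combinations of treatment and time and 28 libraries in all. The series was made to follow over time how messenger RNAs, microRNA targets among them, respond to ABA. The deposited values are the authors' pooled FPKM, 1 per gene and group, so that no value below has a replicate error and the spread between the 2 libraries of a group could not be measured. Between 18634 and 18930 genes reached 1 FPKM in a pool, the pools summed to 903608 to 1173233 FPKM, and the steps between low values implied about 34600000 to 50300000 fragments per pool. The 10 most abundant genes took 5.39 to 11.2% of the summed FPKM. Across genes, which are not independent replicates, the ABA and mock pools of a time correlated with Pearson's r between 0.886 and 0.964, lowest at 3 h and highest at 0.5 h. Effects below are differences of log2(FPKM + 1), ABA minus mock, unless a log2 ratio is named.

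The first question was how many genes differed between ABA and mock at each time. The authors' deposited table called 4352 genes different at 0.5 h (2074 higher and 2278 lower under ABA), 5215 at 1 h (3139 and 2076) and 9074 at 3 h (5012 and 4062). The count in the authors' deposited table was 8839 at 6 h (4475 and 4364), 7287 at 9 h (3571 and 3716), 7438 at 12 h (3779 and 3659) and 7674 at 24 h (3885 and 3789). Among these, the genes that also differed at least 2-fold on the log2(FPKM + 1) scale numbered 1016 at 0.5 h, 3306 at 3 h and 2145 at 24 h in the authors' deposited table. Of 15080 genes called at some time in the authors' deposited table, 3800 were called at 1 time, 716 were called higher at all 7 times and 392 lower at all 7.

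**Figure D1:**
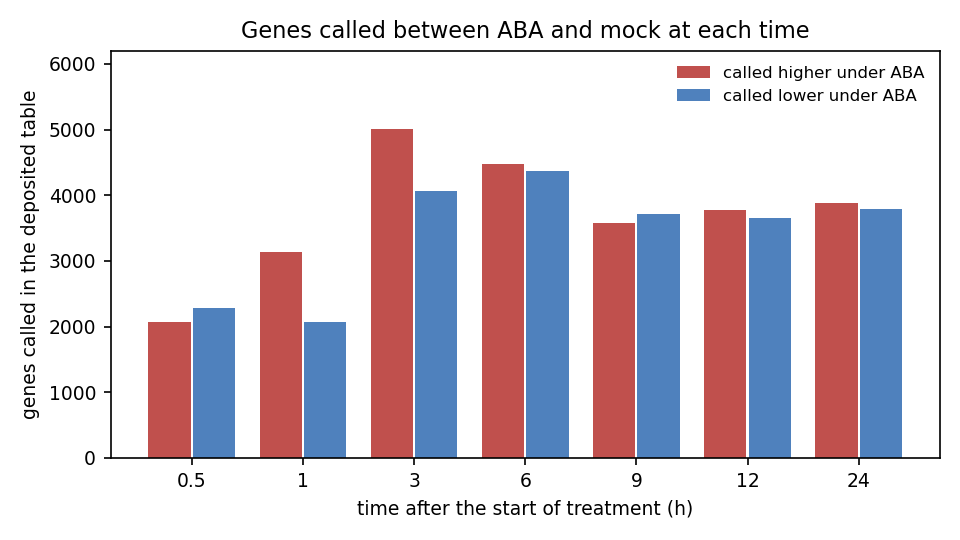
Genes called higher (left bars) and lower (right bars) under ABA in the authors' deposited table at each hour of treatment, counted in genes. The count of called genes rose from 4352 at 0.5 h to 9074 at 3 h and stood at 7674 at 24 h.

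After 0.5 h of ABA, the 9 clade A PP2C phosphatases, which encode negative regulators of ABA signalling, were 9 of 9 called higher in the authors' deposited table, with a median log2 effect of 2.73. The largest rises among abundant genes were PUB19 from 0.556 to 109.7 FPKM (log2 effect 6.15), which encodes a U-box ubiquitin ligase, HAI1 from 0.930 to 126 FPKM (log2 effect 6.03), a PP2C, and DIP2 from 0.978 to 92.0 FPKM (log2 effect 5.55). Among receptor genes, PYL6 fell from 42.8 to 0.194 FPKM (log2 effect -5.20), PYL4 and PYL5 had log2 effects of -3.54 and -3.27, and 6 of 14 receptor genes were called lower against 2 higher in the authors' deposited table. Other large falls among called genes were AT1G72416 from 103 to 3.23 FPKM (log2 effect -4.61) and AT2G15128, which went from 19.8 FPKM to a value listed at 0.

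Of the 18 LEA, dehydrin and cold-regulated genes, whose products protect drying cells, 17 were called higher at 0.5 h in the authors' deposited table, with a median of 1.79. They were led by LEA4-5 (4.40), RD29B (3.74) and RD29A (3.499). ABA- and drought-related transcription factors had 15 of 20 genes called higher and 3 lower in the authors' deposited table, with MYB102 at 4.16 and MYB74 at 3.87. Hypoxia genes fell early, with 8 of 10 called lower and a median of -2.17 in the authors' deposited table. Among them were alcohol dehydrogenase ADH1 from 134 to 19.6 FPKM (log2 effect -2.71) and the transcription factor gene HRE1 (-2.41). The jasmonate list had 13 of 20 members called higher, including JAZ1 from 27.9 to 109 FPKM (log2 effect 1.92), a repressor of jasmonate signalling, and LOX4 (2.07), in the authors' deposited table. Of 11 touch and early stress genes, 7 were called higher in the authors' deposited table. The cold-response regulators CBF1, CBF2 and CBF3 had log2 effects of 4.37, 3.63 and 4.52, which are uncertain because these neighbouring copies share reads.

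At 1 h the LEA, dehydrin and cold-regulated genes were 18 of 18 called higher in the authors' deposited table, with a median log2 effect of 3.95. The leading genes among genes called in the authors' deposited table were HAI1 from 0.915 to 289 FPKM (log2 effect 7.24), LEA4-5 from 7.97 to 1154 FPKM (log2 effect 7.01) and RD20 from 1.31 to 243 FPKM (log2 effect 6.73), which encodes a caleosin. PYL6 and PYL4 showed the largest falls among genes called in the authors' deposited table, PYL6 from 42.3 to 0.458 FPKM (log2 effect -4.89) and PYL4 from 278 to 10.01 FPKM (log2 effect -4.66), followed by AT5G61590 from 362 to 24.8 FPKM (log2 effect -3.81). PP2C genes had a median of 3.86, with 8 of 9 called higher in the authors' deposited table. HAI3 was not called at 1 h although its pooled value was 0.103 FPKM in mock and 49.8 FPKM under ABA. Hypoxia genes were 9 of 10 called lower (median -1.15) and jasmonate genes 15 of 20 called higher (median 0.98) in the authors' deposited table. In the osmolyte list, galactinol synthase GOLS2 rose from 0.580 to 119.7 FPKM and proline synthesis gene P5CS1 from 19.4 to 241 FPKM, while proline dehydrogenase PRODH1 fell from 442 to 75.5 FPKM, each called in the authors' deposited table. Type-A cytokinin response regulators, which dampen cytokinin signalling, were 6 of 9 called lower and 0 higher in the authors' deposited table, with ARR7 at -1.30. Gibberellin genes were 2 of 12 called higher and 4 lower in the authors' deposited table (median -0.41). Of these called genes, the inactivating enzyme gene GA2OX6 rose (2.31) and GA2OX8 (-1.76) and the synthesis gene GA3OX2 (-1.16) fell.

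The 3 h samples held the most called genes, and the LEA group had 18 of 18 genes called higher in the authors' deposited table, with a median log2 effect of 5.79. COR15A rose from 14.5 to 7199.7 FPKM (8.86), RD20 from 2.09 to 1624 FPKM (9.04), and the lipid transfer protein gene LTP4 from a value listed at 0 to 954 FPKM. LTP3 and LTP4 are near-identical neighbours, so their split is uncertain. The largest falls were PYL6 from 92.6 to 0.199 FPKM (log2 effect -6.29), EARLI1 from 447 to 4.99 FPKM (log2 effect -6.23) and AT1G27020 from 160.0 to 1.45 FPKM (log2 effect -6.04). EARLI1 belongs with AZI1, AT4G12490 and AT4G12500 to a cluster of similar genes whose separate values are uncertain. All 4 ABA catabolism genes, which encode ABA 8'-hydroxylases, were called higher in the authors' deposited table, with CYP707A1 at 186 against 8.64 FPKM. Biosynthesis genes had 5 of 10 called higher in the authors' deposited table, led by NCED3, the rate-limiting enzyme of stress-induced ABA synthesis (3.73).

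Photosynthesis genes moved at 3 h, with 17 of 29 called lower and 0 higher in the authors' deposited table and a median of -0.42. RBCS1B, a Rubisco small subunit whose copies share reads, fell from 2489 to 311 FPKM, and RCA, Rubisco activase, from 4717 to 2498 FPKM. Chlorophyll breakdown and senescence genes had 9 of 14 called higher and 1 lower in the authors' deposited table. The sugar transporter gene SWEET15 went from 5.51 to 879 FPKM (log2 effect 7.08) and PAO from 28.99 to 164 FPKM (log2 effect 2.46). In the hypoxia list 3 genes were called higher and 4 lower in the authors' deposited table. ADH1 was now higher (63.6 against 481 FPKM under ABA), while HRE1 (-2.35) and HRE2 (-2.06) stayed lower. Heat shock genes were split, with 6 of 11 called higher, such as HSP17.4 (3.79), and 3 lower in the authors' deposited table. Auxin response genes had 7 of 20 called higher and 2 lower, with a median of 0.54, and the auxin-conjugating enzyme gene GH3.3 rose from 6.95 to 36.9 FPKM in the authors' deposited table. Of 79 microRNA targets, 20 were called higher and 10 lower in the authors' deposited table, among them LAC12 (3.85), NFYA5 (2.81) and LAC13 (2.32). The share called among all tested genes at 3 h was larger.

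At 6 h the largest rises among genes called in the authors' deposited table were RD29B from 0.422 to 664 FPKM (log2 effect 8.87), LEA7 from 4.78 to 2160.4 FPKM (log2 effect 8.55) and TSPO from 0.492 to 507 FPKM (log2 effect 8.41), the last encoding a stress-induced membrane protein. LTP4 had larger effects that were not called at 6, 9 and 12 h (10.61, 10.43 and 10.68). The largest falls among genes called in the authors' deposited table were EARLI1 from 715 to 7.80 FPKM (log2 effect -6.35), AT1G27020 from 135 to 1.27 FPKM (log2 effect -5.91) and AT4G12490 from 82.4 to 1.66 FPKM (log2 effect -4.97). Photosynthesis genes stayed lower, with 17 of 29 called lower and 1 higher in the authors' deposited table (median -0.49). Cell cycle genes had 10 of 23 called lower and 0 higher in the authors' deposited table. The replication clamp gene PCNA1 had a log2 effect of -1.02 and CDC20.2 of -0.92. Salicylate defence genes were 8 of 15 called lower and 0 higher in the authors' deposited table, with CBP60G falling from 9.83 to 0.264 FPKM and ICS1, which makes the salicylate precursor, from 15.6 to 3.42 FPKM. Seed storage and oil body genes had 6 of 10 called higher in the authors' deposited table, among them oleosin OLEO2 (0.587 to 60.8 FPKM) and PER1 (3.86). Aquaporins, the water channels, were 13 of 18 called higher in the authors' deposited table, with TIP2;3 at 2.44 and PIP2;5 at 1.36. Of 22 small RNA machinery genes, 5 were called lower, including the microRNA-degrading nuclease gene SDN1 (-1.21), and 1 higher in the authors' deposited table. SnRK2 kinase and ABF/ABI genes had 8 of 13 members called higher in the authors' deposited table, led by ABF3 (2.08).

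At 9 h salicylate defence genes were lower under ABA: 9 of 15 were called lower and 0 higher in the authors' deposited table, with a median log2 effect of -1.98. ICS1 stood at 55.8 FPKM in mock and 4.12 FPKM under ABA, the transcription factor gene WRKY70 at 30.4 and 1.06 FPKM, and FMO1 at 12.4 and 0.376 FPKM. The largest falls among genes called in the authors' deposited table were EARLI1 from 1244 to 7.18 FPKM (log2 effect -7.25), AT4G12490 from 354 to 1.83 FPKM (log2 effect -6.97) and AIG1 from 67.9 to 0.292 FPKM (log2 effect -5.74). The largest rises among genes called in the authors' deposited table were RD29B from 0.455 to 439.9 FPKM (log2 effect 8.24), AT2G37870 from 2.25 to 871 FPKM (log2 effect 8.07) and AT3G02480 from 30.0 to 7324 FPKM (log2 effect 7.88). Jasmonate genes had 9 of 20 called lower and 5 higher in the authors' deposited table. The repressor gene JAZ6 had a log2 effect of -2.31, whereas VSP2 had 2.89 and VSP1 1.997, a near-identical pair whose values are uncertain. Among root markers 5 were called higher and 5 lower of 18 in the authors' deposited table. The iron transporter gene IRT1 fell from 35.03 to 1.19 FPKM. Guard cell markers had 1 of 6 called lower and 0 higher in the authors' deposited table, the called gene being MYB60 (-1.14).

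At 12 h photosynthesis genes were higher under ABA, with 18 of 29 called higher and 3 lower in the authors' deposited table and a median log2 effect of 0.59. PSBO2 stood at 509.7 FPKM in mock and 1163 FPKM under ABA and PETE1, plastocyanin, at 71.2 and 158 FPKM, while RBCS3B stayed lower (-0.998). From 0.5 to 12 h the list's median level went from 4984 to 1174 FPKM in mock and from 4594 to 1755 FPKM under ABA. Both had thus fallen, the mock level further. The largest rises at 12 h among genes called in the authors' deposited table were AT2G37870 from 2.12 to 1199 FPKM (log2 effect 8.59), LEA7 from 4.27 to 1414 FPKM (log2 effect 8.07) and the dehydrin RAB18 from 6.70 to 1772 FPKM (log2 effect 7.85). The largest falls among genes called in the authors' deposited table were AT4G12490 from 569 to 0.945 FPKM (log2 effect -8.19), EARLI1 from 1657 to 13.1 FPKM (log2 effect -6.88) and AIG1 from 90.3 to 0.251 FPKM (log2 effect -6.19). Salicylate defence genes were 11 of 15 called lower in the authors' deposited table (median -1.94), and touch genes 5 of 11, including the calmodulin-like gene CML12, which fell from 117 to 4.14 FPKM. Aquaporins had 13 of 18 called higher in the authors' deposited table, with TIP2;3 at 2.19 and PIP1;1 at 1.66. The microRNA targets had 18 genes called higher and 7 lower in the authors' deposited table, with NFYA5 at 2.35 and LAC17 at 1.85. Clock genes were 6 of 25 called higher and 1 lower in the authors' deposited table, with CDF1 at 1.77 and BOA at 1.29.

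At 24 h LEA7 still stood at 1211 FPKM under ABA and 3.25 FPKM in mock (8.16), AT2G37870 at 1227 and 4.56 FPKM (7.79), and LTP4 at 2058 and 0.504 FPKM (10.42). The largest falls among genes called in the authors' deposited table were AT4G12490 from 556 to 0.513 FPKM (log2 effect -8.52), AT4G33720 from 106 to 0.431 FPKM (log2 effect -6.22) and EARLI1 from 1596 to 20.99 FPKM (log2 effect -6.18). Type-A cytokinin response regulators were 6 of 9 called lower and 0 higher in the authors' deposited table (median -1.39), with ARR5 at -1.93 and ARR7 at -1.67. Cell wall loosening genes had 9 of 13 called lower in the authors' deposited table, among them the expansin EXPA1, which fell from 281 to 37.1 FPKM. Seed storage and oil body genes had 5 of 10 called higher in the authors' deposited table, with OLEO2 at 4.92. Photosynthesis genes had 12 of 29 called higher and 5 lower in the authors' deposited table. Among microRNA targets 26 were called higher and 6 lower in the authors' deposited table. NFYA5 and LAC17 were higher (2.32 and 2.23), while the copper/zinc superoxide dismutase genes CSD1 and CSD2 were lower (-1.75 and -2.07). Small RNA machinery genes had 10 of 22 called higher and 0 lower in the authors' deposited table, with AGO4 at 0.81, DCL1 at 0.77 and SGS3 at 0.72.

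The 24 h effect rose with transcript length across genes, with Spearman's rho of 0.333 over 14477 genes, and its median was -0.32 for transcripts under 500 bases and 0.35 for those over 3000. At the other times rho lay between -0.0545 and 0.0799. The microRNA targets had a median length of 2104 bases, and their 24 h median of 0.25 became 0.08 once the length trend was removed. Among random lists matched on abundance, the median of the targets before removal stood at percentile 99.93. Among lists matched on length as well it still stood at 99.46. For the small RNA machinery, with a median length of 3349.5 bases, the 24 h median went from 0.33 to -0.08. The same removal moved cell wall loosening from -0.74 to -0.59, photosynthesis from 0.27 to 0.37, type-A cytokinin response regulators from -1.39 to -1.33 and seed storage genes from 1.79 to 2.09. Other lists moved too, among them ABA biosynthesis from 0.81 to 0.50, clock genes from 0.23 to 0.08 and jasmonate genes from -0.06 to -0.18. The medians of auxin response (-0.12 to 0.02) and osmolyte genes (0.0075 to -0.10) changed sign.

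**Figure D2:**
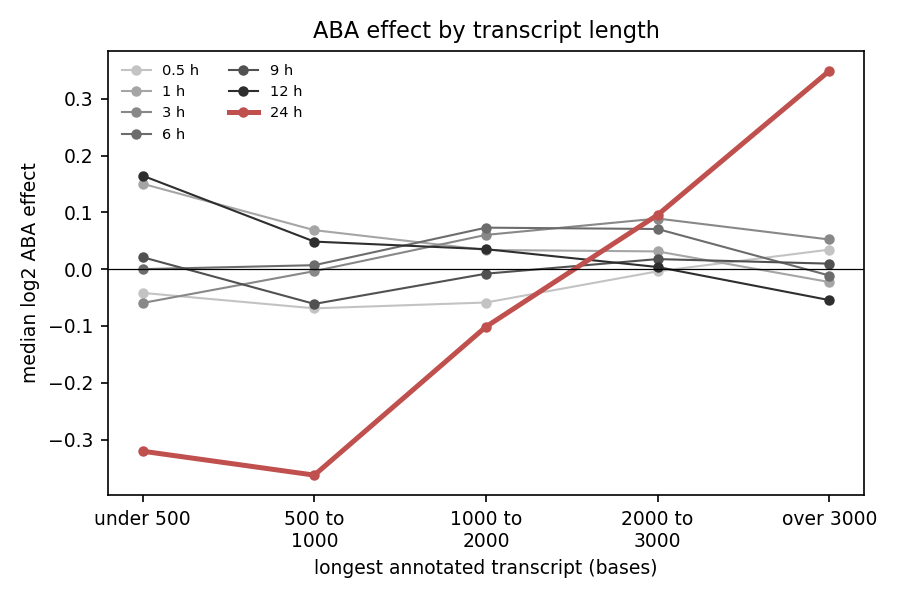
Median log2 effect of ABA (difference of log2(FPKM + 1), vertical axis) of genes grouped by transcript length in bases (horizontal axis), with 1 line per time. At 24 h the median rose from -0.32 in the shortest class to 0.35 in the longest.

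Genes of the ABA pathway itself were followed through all times. At 0.5, 1, 3, 6, 9, 12 and 24 h the log2 effects of RD29A were 3.499, 5.93, 5.78, 6.17, 5.10, 3.78 and 4.55, those of RD29B 3.74, 5.81, 8.81, 8.87, 8.24, 7.83 and 7.49 and those of RAB18 1.53, 3.504, 7.58, 8.17, 7.31, 7.85 and 7.36, in that order. Among the phosphatases, HAI1 gave 6.03, 7.24, 7.43, 6.35, 5.95, 5.80 and 4.97, ABI1 2.68, 3.17, 3.62, 2.90, 2.76, 2.47 and 2.096 and ABI2 2.73, 4.05, 4.40, 3.61, 3.21, 3.16 and 2.98 at those 7 times. The receptor genes PYL4 and PYL5 were lower throughout, PYL4 at -3.54, -4.66, -4.84, -4.85, -4.32, -4.14 and -3.34 and PYL5 at -3.27, -3.22, -3.42, -3.61, -3.86, -3.09 and -3.52. PYL6 gave -5.20, -4.89, -6.29, -6.02, -5.93 and -5.73 up to 12 h and was listed at 0 under ABA at 24 h, against 63.7 FPKM in mock. The catabolic gene CYP707A1 gave 2.49, 3.46, 4.28, 3.97, 3.66, 3.36 and 3.53, and CYP707A3 gave 0.04, -0.39, 2.11, 1.80, 1.53, 1.63 and 1.61, lower at 1 h and higher from 3 h on by the calls of the authors' deposited table. NCED3 gave 3.66, 3.68, 3.73, 3.24, 3.17, 3.07 and 2.80 and the transcription factor gene ABI5 0.90, 1.77, 2.36, 1.92, 1.47, 1.03 and 1.39. Each of these genes was called at all 7 times in the authors' deposited table, except CYP707A3 at 0.5 h and PYL6 at 6, 9 and 12 h.

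The clock gene CCA1 gave 0.40, 0.76, -0.08, 0.12, -0.14, 0.65 and 0.24 and was called higher at 0.5, 1 and 12 h in the authors' deposited table, and TOC1 gave 0.44, 0.34, 0.39, 0.30, 0.23, -0.10 and 0.23 and was called higher at 0.5 and 3 h. Of genes tied to microRNAs, AGO1, the effector of microRNA action, gave 0.07, 0.13, 0.16, 0.05, 0.07, 0.19 and 0.41 and DCL1, which processes their precursors, -0.07, -0.13, -0.01, -0.11, -0.03, -0.32 and 0.77, both called at 24 h alone in the authors' deposited table. MYB33 gave 0.01, 0.25, 0.41, 0.34, 0.14, 0.11 and 0.32, called at 3 h alone in the authors' deposited table, and CSD1 -0.07, -0.01, -0.32, -0.64, -1.49, -1.52 and -1.75, called lower from 6 h on. MYB101 lay below 1 FPKM in every pool, between 0.140 and 0.585 FPKM, with effects of -0.33, -0.35, -0.38, -0.26, -0.08, -0.17 and 0.04, none of them called in the authors' deposited table.

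**Figure D3:**
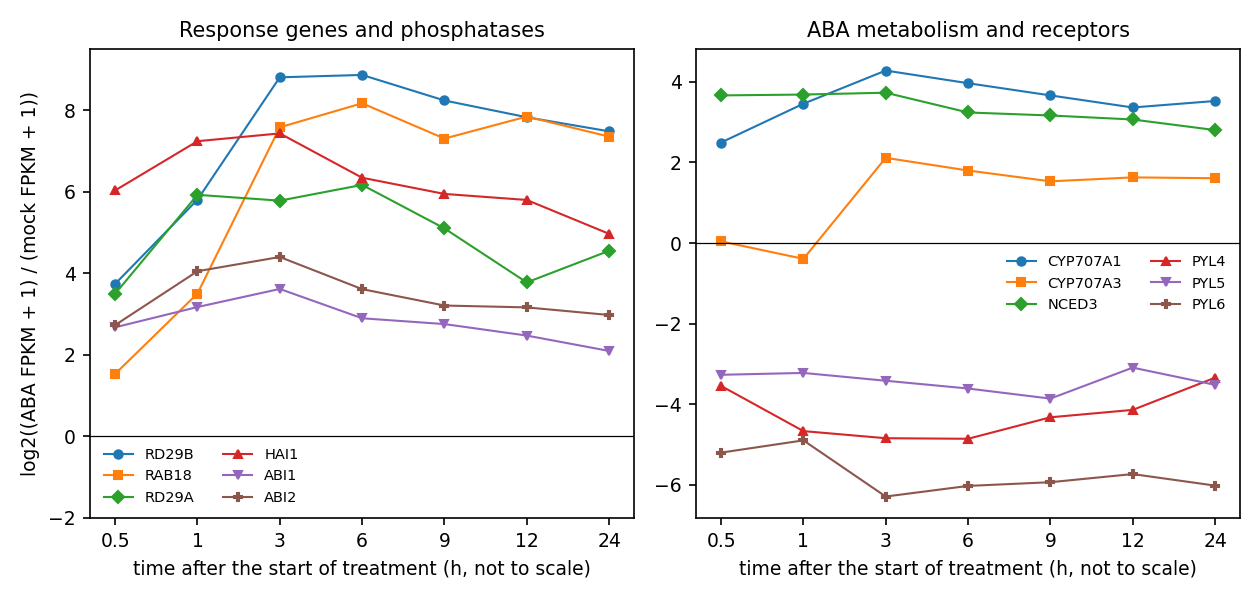
Log2 effect of ABA (difference of log2(FPKM + 1)) against hours of treatment (evenly spaced, not to scale) for genes of ABA signalling and ABA turnover, 1 line per gene. HAI1 lay between 4.97 and 7.43 at all times, and PYL4 between -4.85 and -3.34.

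Averaged over the 7 times, the largest rises were those of LTP4, RD29B and LEA4-5. RD29B had a mean log2 effect of 7.26 ± 0.58 (SE, n = 7 times; limma adjusted p = 5.59e-05), LEA4-5 of 7.14 ± 0.46 (adjusted p = 1.64e-05) and LTP4 of 8.52 ± 1.001 (adjusted p = 3.40e-04), each higher at 7 of 7 times. The means of LTP4 and PYL6 include 1 pool listed at 0 and so depend on the pseudocount. PYL6 lay below 1 FPKM under ABA at all 7 times, so its mean and SE depend on the pseudocount at each of them. Its log2 ratios up to 12 h ran from -6.53 at 1 h to -9.88 at 6 h. LEA7 (7.07), TSPO (6.74), AT3G17520 (6.45), AT2G37870 (6.38), RD20 (6.36), HAI1 (6.25) and COR15A (6.24) completed the 10 largest rises. The largest falls were PYL6 at -5.73 ± 0.16 (limma adjusted p = 6.60e-07), EARLI1 at -5.49 ± 0.59 (adjusted p = 2.10e-04) and AT4G12490 at -5.08 ± 0.93 (adjusted p = 0.00278). They were followed by AT1G27020 (-4.26), PYL4 (-4.24), AT5G64120 (-4.18), AT4G12500 (-4.06), AZI1 (-3.99), AT3G16530 (-3.77) and AT2G43140 (-3.72). In limma over 20034 genes, 9417 passed an adjusted p of 0.05, 4779 higher and 4638 lower, and 1877 of them also averaged at least 2-fold. The spread in this test is that between times, so it holds real change over time as well as error, and not the spread between libraries. It also takes the 7 times as independent, although they form 1 series.

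ABA signalling lists moved as groups. All 18 LEA, dehydrin and cold-regulated genes rose (median 4.24; limma camera adjusted p = 3.11e-11, adjusted p = 0.345 with an estimated correlation), as did all 9 clade A PP2C genes (median 3.45; camera adjusted p = 3.76e-09, adjusted p = 0.345 with an estimated correlation), with HAI1, HAI3 (5.62), HAI2 (5.09) and PP2CA (4.19) in front. Adjusted over the list alone, these counts were 18 and 9. Of 9 tested receptor genes, 7 fell and 0 rose, also 7 when adjusted over the list alone (median -1.11; camera adjusted p = 4.36e-05, adjusted p = 0.345 with an estimated correlation). PYL5 averaged -3.43 and PYR1 -1.89. Transcription factors had 14 rises and 5 falls of 20, 15 and 5 adjusted over the list alone (median 1.198; camera adjusted p = 5.03e-04, adjusted p = 0.349 with an estimated correlation), led by ATHB7 (5.11), ATHB12 (4.11), MYB102 (3.93) and ANAC019 (3.64). SnRK2 and ABF/ABI genes had 7 rises of 10, 7 adjusted over the list alone (median 0.71; camera adjusted p = 5.96e-04, adjusted p = 0.345 with an estimated correlation), with ABF3 at 2.09, ABF2 at 1.85, ABI5 at 1.55 and ABF4 at 0.95. The 4 ABA catabolism genes rose, 4 adjusted over the list alone (median 1.67; camera adjusted p = 0.00259, adjusted p = 0.349 with an estimated correlation), from 1.19 for CYP707A3 and 1.31 for CYP707A2 to 2.03 for CYP707A4 and 3.54 for CYP707A1. Of 6 biosynthesis genes 4 rose, 4 adjusted over the list alone (median 0.79; camera adjusted p = 0.0337, adjusted p = 0.349 with an estimated correlation), which were NCED3 (3.34), AAO3 (0.93), ABA1 (0.81) and BGLU18 (0.76).

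Other lists passed the same limma camera test. Aquaporins had 14 rises and 1 fall of 18, 14 and 1 adjusted over the list alone (median 0.60; camera adjusted p = 1.09e-04, adjusted p = 0.345 with an estimated correlation), with TIP2;3 at 1.95, PIP1;1 at 1.102, PIP2;1 at 1.09 and PIP2;5 at 0.98. Seed storage and oil body genes had 6 rises of 8, 6 adjusted over the list alone (median 1.07; camera adjusted p = 0.00259, adjusted p = 0.345 with an estimated correlation), with OLEO2 at 4.26, PER1 at 3.66, OLEO1 at 3.29 and CRA1 at 1.36. Senescence genes had 7 rises and 1 fall of 13, 7 and 1 adjusted over the list alone (median 0.69; camera adjusted p = 0.0366, adjusted p = 0.349 with an estimated correlation), with SWEET15 at 5.20 and the chlorophyll breakdown genes PAO, SGR1 and PPH at 1.71, 1.29 and 0.91. Cell cycle genes had 12 falls and 1 rise of 23, 12 and 1 adjusted over the list alone (median -0.26; camera adjusted p = 0.00259, adjusted p = 0.451 with an estimated correlation), with PCNA1 at -0.65, MCM5 at -0.52, MCM2 at -0.47 and CDC20.2 at -0.46. Salicylate defence genes had 6 falls of 13, 6 adjusted over the list alone (median -1.08; camera adjusted p = 0.0153, adjusted p = 0.57 with an estimated correlation), with WRKY70 at -2.005, CBP60G at -1.62, ICS1 at -1.44 and FMO1 at -1.35. With a single time left out, the limma calls of CBP60G and FMO1 were lost without 3, 6, 9, 12 or 24 h (means of -1.34 to -1.61 and -0.97 to -1.48) and that of ICS1 without 6 or 12 h (-1.19 to -1.36). The calls of CBP60G and FMO1 were also lost with a pseudocount of 5 (means of -0.74 and -0.62) or with no filter on low values (-1.62 and -1.35). The list gave a camera adjusted p of 0.0563 with genes of at least 5 FPKM in at least 4 pools, and with fry its adjusted p was 0.0754.

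Hypoxia genes had 5 falls and 1 rise of 10, 5 and 1 adjusted over the list alone (median -0.51; limma camera adjusted p = 0.0417, adjusted p = 0.498 with an estimated correlation), with HRE2 at -2.05, HRE1 at -2.03 and PGB1 at -1.11, while sucrose synthase SUS1 rose (1.23). The SUS1 call was lost with no filter on low values. Type-A cytokinin response regulators had 6 falls and 1 rise of 9, 7 and 1 adjusted over the list alone (median -0.57; camera adjusted p = 0.0366, adjusted p = 0.383 with an estimated correlation), with ARR7 at -1.36, ARR15 at -1.16, ARR5 at -0.83 and ARR6 at -0.70. Without 24 h the camera adjusted p of this list was 0.0634 and without 1 h 0.076, and for hypoxia it was 0.133 without 0.5 h, 0.0871 without 1 h and 0.0707 after quantile normalization. Without 3, 6, 9, 12 or 24 h the limma calls of SUS1 (means of 0.87 to 1.33) and ARR5 (-0.65 to -0.85) were lost. Cell wall loosening genes had 5 falls and 1 rise of 13, 5 and 1 adjusted over the list alone (median -0.40; camera adjusted p = 0.039, adjusted p = 0.345 with an estimated correlation), with EXPA1 at -2.41, EXPA8 at -1.68, XTH4 at -0.66 and EXPA15 at -0.65. Without 24 h that adjusted p was 0.0781. The camera calls above used a preset correlation of 0.01 between genes, and none of the 15 held with an estimated correlation. That correlation was estimated from the spread between times, which holds real change over time. With fry, which does not compare a list with other genes, all of these lists but salicylate defence passed in the same direction. The fry adjusted p was 3.26e-04 for LEA genes, 3.26e-05 for clade A PP2C genes and 3.01e-05 for receptors.

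The other 12 lists did not pass limma's camera over all times. With fry, clock genes (adjusted p = 0.00124), guard cell markers (adjusted p = 0.00363) and osmolyte genes (adjusted p = 3.26e-04) passed. MicroRNA targets had 23 rises and 13 falls of 73 (23 and 14 adjusted over the list alone; median 0.06; camera adjusted p = 0.396), with NFYA5 at 1.94, LAC12 at 1.44, ANAC100 at 1.40 and CSD2 at -1.38. Small RNA machinery had 1 rise and 7 falls of 22 (1 and 7 adjusted over the list alone; median -0.12; camera adjusted p = 0.21), with SDN1 at -0.61, AGO7 at 0.38, AGO2 at -0.34 and HYL1 at -0.27. Without 24 h, where effects rose with transcript length, the limma camera adjusted p of the small RNA machinery was 0.0485. Clock genes had 7 rises and 2 falls of 25 (7 and 2 adjusted over the list alone; median 0.23; camera adjusted p = 0.137), with CDF1 at 1.55, BOA at 1.22, LNK1 at 1.01 and RVE6 at 0.82. Osmolyte genes had 5 rises and 3 falls of 10 (5 and 3 adjusted over the list alone; median 0.27; camera adjusted p = 0.204), with GOLS2 at 4.30, P5CS1 at 3.78, DIN10 at -1.53 and GOLS1 at 1.21. Heat shock genes had 6 rises and 3 falls of 11 (6 and 3 adjusted over the list alone; median 0.79; camera adjusted p = 0.441), with HSP22 at 3.92, HSP17.4 at 2.23, HSP90.1 at -1.61 and HSP18.2 at 1.42. Jasmonate genes had 6 rises and 2 falls of 19 (6 and 2 adjusted over the list alone; median 0.17; camera adjusted p = 0.328), with VSP2 at 2.75, JAZ6 at -1.64, VSP1 at 1.51 and JAZ7 at 1.24. Touch genes had 3 rises and 3 falls of 11 (3 and 4 adjusted over the list alone; median -0.39; camera adjusted p = 0.545), with CML12 at -3.04, CBF3 at 2.89, CBF1 at 1.78 and CBF2 at 1.70. Photosynthesis genes had 1 rise and 5 falls of 29 (1 and 5 adjusted over the list alone; median -0.04; camera adjusted p = 0.417), with RBCS1B at -1.36, RBCS2B at -0.69, RBCS3B at -0.64 and PETE1 at 0.58.

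In limma over all times, auxin response genes had 3 rises and 4 falls of 17 (3 and 4 adjusted over the list alone; median 0.13; camera adjusted p = 0.974), with SAUR15 at -1.39, GH3.5 at 1.07, GH3.6 at 0.83 and IAA1 at -0.60. Gibberellin genes had 3 rises and 4 falls of 10 (3 and 4 adjusted over the list alone; median 0.10; camera adjusted p = 0.845), with GA2OX6 at 1.15, GA2OX2 at -0.91, GA3OX2 at -0.85 and GA2OX8 at -0.56. Their median was above 0 while their mean of -0.04 and the direction of the test were below it. Root markers had 7 rises and 5 falls of 18 (8 and 5 adjusted over the list alone; median 0.23; camera adjusted p = 0.424), with IRT1 at -2.58, PRP3 at 1.01, HKT1 at -0.89 and LRX1 at 0.86. Guard cell markers had 0 rises and 3 falls of 6 (1 and 4 adjusted over the list alone; median -0.26; camera adjusted p = 0.189), with MYB60 at -1.07, EPF1 at -0.49 and FAMA at -0.27. Among the genes of these 12 lists, calls were lost for LAC12 without 6, 9 or 12 h (means of 1.34 to 1.43), HYL1 without 6 h (-0.24), GA2OX8 without 9, 12 or 24 h (-0.57 to -0.58), EPF1 without 3, 6 or 12 h (-0.40 to -0.45) and FAMA without 3, 6, 9 or 12 h (-0.23 to -0.28). They were also lost for CBF1 (0.98) and CBF2 (1.06) with a pseudocount of 5 and for RBCS3B (-0.64) with no filter on low values. HSP22 and HAI3 lay near 0 FPKM in mock, so their log2(FPKM + 1) effects understate the ratio.

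**Figure D4:**
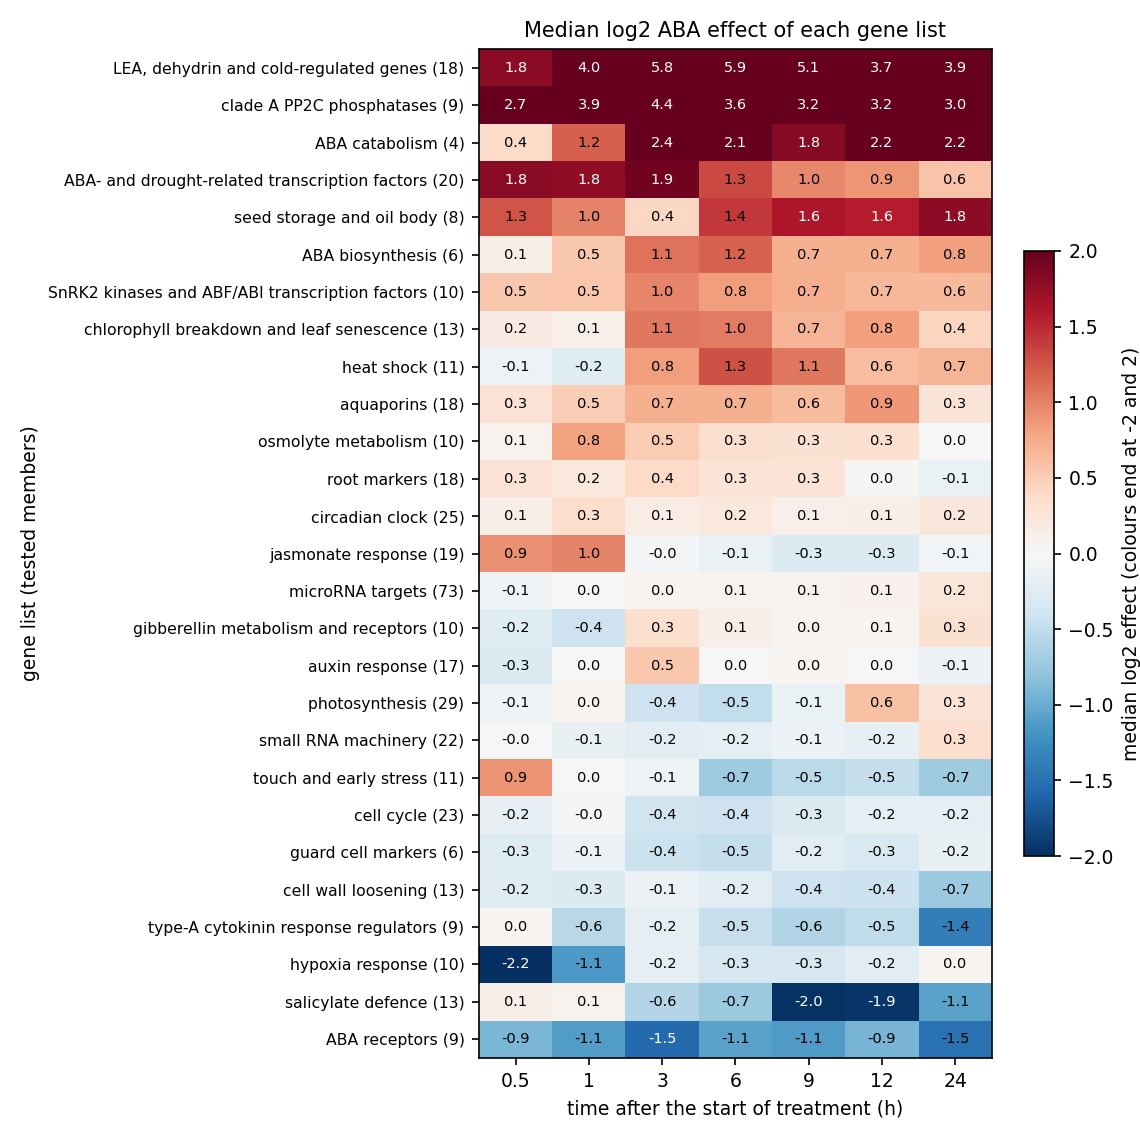
Median log2 effect of ABA (colour, difference of log2(FPKM + 1), with colours ending at -2 and 2) for each gene list (vertical axis) at each hour of treatment (horizontal axis). The LEA list went from 1.79 at 0.5 h to 5.94 at 6 h, and the salicylate list from 0.12 at 0.5 h to -1.98 at 9 h.

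Whether the ABA effect differed between late (9, 12 and 24 h) and early times (0.5 and 1 h) was tested directly. The lists of salicylate defence, jasmonate and touch genes passed limma's camera toward lower late effects and those of hypoxia, LEA and heat shock genes toward higher ones. None of these calls held with an estimated correlation. LTP4 gained 6.72 ± 0.25 on the log2 scale (SE; limma adjusted p = 4.62e-05), AT3G02480 5.47 ± 0.52 (adjusted p = 0.00119), AT2G37870 5.40 ± 0.62 (adjusted p = 0.00186) and LTP3 5.26 ± 0.32 (adjusted p = 3.30e-04). The chloroplast gene ATCG01020 also passed (8.23, limma adjusted p = 0.0295), but it was listed at 0 in most pools, and its call was lost without 0.5, 1, 9 or 12 h (differences of 6.41 to 9.14) or with no filter on low values. The largest declines that passed were AT4G12490 at -6.51 ± 0.57 (limma adjusted p = 8.89e-04), AT4G12500 at -5.58 ± 0.46 (adjusted p = 7.09e-04), AIG1 at -5.32 ± 0.59 (adjusted p = 0.00169), AT3G22235 at -5.22 ± 0.72 (adjusted p = 0.00398) and AT3G47480 at -4.80 ± 0.67 (adjusted p = 0.0042). Their mock values were low early and high late, as for AIG1, which went from 0.468 FPKM at 0.5 h to 90.3 FPKM at 12 h in mock and from 0.242 to 0.251 FPKM under ABA. In limma 2875 of 20034 genes passed an adjusted p of 0.05, 1328 with a higher and 1547 with a lower late effect. Without 0.5 h the count was 1249, without 1 h 1333 and without 12 h 1651.

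In limma, salicylate defence genes had 0 higher and 9 lower late effects of 13, 0 and 12 adjusted over the list alone (median -2.18; camera adjusted p = 7.95e-07, adjusted p = 0.415 with an estimated correlation). WRKY70 had a difference of -2.50 and CBP60G of -3.40. Jasmonate genes had 1 higher and 13 lower late effects of 19, 2 and 15 adjusted over the list alone (median -1.11; camera adjusted p = 4.32e-06, adjusted p = 0.349 with an estimated correlation), JAZ6 among them (-1.26). Touch and early stress genes had 0 higher and 6 lower late effects of 11, 0 and 8 adjusted over the list alone (median -1.46; camera adjusted p = 9.07e-06, adjusted p = 0.415 with an estimated correlation), with CML12 at -4.00 and CBF1 at -3.30. Hypoxia genes had 6 higher and 0 lower late effects of 10, 8 and 0 adjusted over the list alone (median 0.996; camera adjusted p = 6.22e-05, adjusted p = 0.265 with an estimated correlation), ADH1 among them (3.91, limma adjusted p = 0.00253) and PGB1 (1.43). LEA, dehydrin and cold-regulated genes had 7 higher and 0 lower late effects of 18, 8 and 0 adjusted over the list alone (median 1.13; camera adjusted p = 9.77e-05, adjusted p = 0.605 with an estimated correlation), with RAB18 at 4.99 and RD29B at 3.08. Heat shock genes had 3 higher and 1 lower late effects of 11, 7 and 1 adjusted over the list alone (median 0.70; camera adjusted p = 0.00297, adjusted p = 0.415 with an estimated correlation), with HSP22 at 4.84. ABA catabolism genes had 2 higher and 0 lower late effects of 4, 2 and 0 adjusted over the list alone (median 1.15; camera adjusted p = 0.0064, adjusted p = 0.415 with an estimated correlation), which were CYP707A4 (1.94) and CYP707A3 (1.76).

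A further 4 lists passed limma's camera, and each lost its call without 24 h. MicroRNA targets had 10 higher and 3 lower late effects of 73, 11 and 4 adjusted over the list alone (median 0.13; camera adjusted p = 0.00968, adjusted p = 0.415 with an estimated correlation), and without 24 h the adjusted p was 0.0628. Seed storage and oil body genes had 3 higher and 0 lower late effects of 8, 3 and 0 adjusted over the list alone (median 0.64; camera adjusted p = 0.0174, adjusted p = 0.415 with an estimated correlation), and without 24 h it was 0.115. ABA receptors had 0 higher and 3 lower late effects of 9, 0 and 3 adjusted over the list alone (median -0.38; camera adjusted p = 0.0266, adjusted p = 0.415 with an estimated correlation), against 0.0674 without 24 h, 0.182 without 0.5 h and 0.0626 without 9 h. Transcription factors had 0 higher and 4 lower late effects of 20, 0 and 5 adjusted over the list alone (median -0.70; camera adjusted p = 0.0278, adjusted p = 0.639 with an estimated correlation), against 0.115 without 24 h and 0.0667 without 1 h. Lists that passed with a time left out but not with all times were photosynthesis without 9 h (camera adjusted p = 1.90e-04), type-A cytokinin response regulators without 1 h (0.0172) and root markers without 1 or 9 h (0.0298 and 0.0269). CSD1 had a lower late effect (-1.55, limma adjusted p = 0.00152) and NFYA5 a higher late effect (1.63, adjusted p = 0.0164). Calls were also lost with other settings, for receptors with a pseudocount of 5 (0.0577) or no filter on low values (0.0992), for transcription factors with a pseudocount of 0.1 (0.0515) or no filter (0.0535), for seed genes with no filter (0.119) and for microRNA targets with at least 5 FPKM in at least 4 pools (0.0552). With fry the adjusted p was 0.209 for LEA genes, 0.235 for transcription factors and 0.0826 for microRNA targets, so these late minus early calls were lost. Median, mean and direction of the limma camera test differed in sign for SnRK2 and ABF/ABI genes (-0.07 and 0.05; test upward), clade A PP2C genes (-0.12 and 0.02; test upward), guard cell markers (-0.17 and 0.04; test downward) and osmolyte genes (-0.01 and -0.10; test upward), the numbers being the median and the mean.

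**Figure D5:**
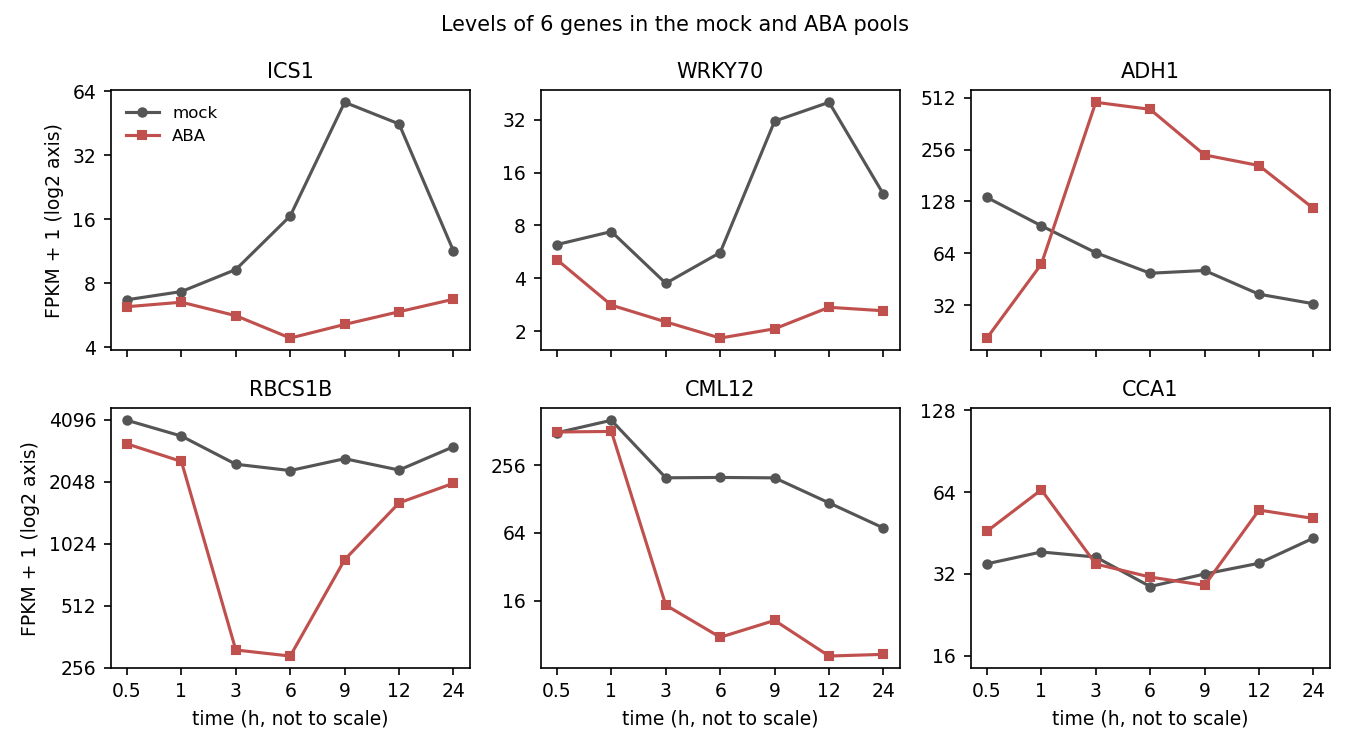
Pooled FPKM + 1 (log2 axis) in mock and ABA seedlings against hours of treatment (evenly spaced, not to scale) for ICS1, WRKY70, ADH1, RBCS1B, CML12 and CCA1. ICS1 in mock went from 5.69 FPKM at 0.5 h to 55.8 FPKM at 9 h and 10.3 FPKM at 24 h, and stayed between 3.42 and 5.73 FPKM under ABA.

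A steady change of the ABA effect over time was tested as its slope on log2 hours. The cold-response regulator CBF1 had a slope of -0.77 per unit of log2 hours (limma adjusted p = 0.00462), from 72.5 FPKM under ABA at 0.5 h to 0.222 FPKM at 24 h. EDL3, an F-box gene of ABA signalling, had a slope of -0.84 (limma adjusted p = 0.00505), going from 49.0 to 2.87 FPKM under ABA, and AT2G22930 one of -0.45. The cell wall invertase gene CWINV5 had a slope of 0.96 (limma adjusted p = 0.00462), going from 0.103 to 30.1 FPKM under ABA, and the chitinase gene ChiC one of 0.49. Falling slopes were also found for AT4G22212 (-0.96), the peroxidase gene Prx37 (-0.68), AT4G29690 (-0.62), AT3G22240 (-0.42) and AT4G36500 (-0.36), each with a limma adjusted p of 0.00505 or less. AT4G29690 was called higher at 0.5 h (1.40) and lower at 24 h (-1.93) in the authors' deposited table. In limma 1044 genes passed, 399 with a rising and 645 with a falling slope. The count went to 266, 82, 466, 196 and 182 without 0.5, 1, 6, 9 and 12 h, and to 490 with no filter on low values. With a pseudocount of 0.1 the call of CBF1 was lost (slope -0.64).

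The mock series showed what changed over 24 h without ABA. The photosynthesis transcript RBCS3B went from 16468 FPKM at 0.5 h to 4500.1 FPKM at 24 h (slope -0.39 per unit of log2 hours, limma adjusted p = 0.00562). Alcohol dehydrogenase ADH1 fell from 134 to 31.6 FPKM (slope -0.36, limma adjusted p = 0.00335), and CML12 from 497 to 69.7 FPKM (-0.52, adjusted p = 0.00558). EARLI1 rose from 184 to 1596 FPKM (0.64, limma adjusted p = 0.00335) and the ascorbate peroxidase gene SAPX from 67.5 to 290.0 FPKM (0.41). Rising slopes with the smallest p-values were also those of AT1G65845 (0.39), AKR4C8 (0.34), AT1G21520 (0.57) and AT3G04000 (0.76), and falling ones those of AT4G27450 (-0.47), AT4G16563 (-0.44) and OFP15 (-0.27), each with a limma adjusted p of 0.00335. In limma 5795 of 20034 genes passed, 2811 with a rising and 2984 with a falling slope. Without 0.5, 1, 9 and 12 h the count was 2526, 2201, 3420 and 3419. Without 24 h, a mock pool whose values fell with transcript length (Spearman's rho -0.395 against the other mock pools), it was 8474.

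In limma, photosynthesis genes had 0 rising and 25 falling slopes of 29, 0 and 27 adjusted over the list alone (median -0.31; camera adjusted p = 1.77e-12, adjusted p = 0.441 with an estimated correlation). Aquaporins had 0 rising and 11 falling slopes of 18, 0 and 16 adjusted over the list alone (median -0.17; camera adjusted p = 3.46e-06, adjusted p = 0.4658 with an estimated correlation), TIP2;3 among them (-0.36). Auxin response genes had 0 rising and 12 falling slopes of 17, 1 and 13 adjusted over the list alone (median -0.21; camera adjusted p = 3.46e-06, adjusted p = 0.333 with an estimated correlation), IAA1 among them (-0.27). Touch and early stress genes had 0 rising and 7 falling slopes of 11, 0 and 9 adjusted over the list alone (median -0.32; camera adjusted p = 1.55e-04, adjusted p = 0.333 with an estimated correlation), and hypoxia genes had 1 rising and 6 falling slopes of 10, 1 and 7 adjusted over the list alone (median -0.23; camera adjusted p = 0.00496, adjusted p = 0.333 with an estimated correlation). Salicylate defence genes had 2 rising and 0 falling slopes of 13, 2 and 0 adjusted over the list alone (median 0.28; camera adjusted p = 0.0133, adjusted p = 0.659 with an estimated correlation), and the rise was not steady, since WRKY70 went from 5.23 FPKM at 0.5 h to 39.2 FPKM at 12 h and 11.04 FPKM at 24 h. Root markers had 0 rising and 2 falling slopes of 18, 0 and 6 adjusted over the list alone (median -0.09; camera adjusted p = 0.0171, adjusted p = 0.333 with an estimated correlation), IRT1 among them (-0.57). LEA, dehydrin and cold-regulated genes had 1 rising and 8 falling slopes of 18, 2 and 9 adjusted over the list alone (median -0.13; camera adjusted p = 0.0174, adjusted p = 0.333 with an estimated correlation), RD29B among them (-0.39). Without 0.5 h the camera adjusted p of the LEA list was 0.0648, and lists that passed with a time left out but not with all times were microRNA targets (0.0376) and type-A cytokinin response regulators (0.0344) without 1 h and the small RNA machinery (0.0183) without 24 h. With genes of at least 5 FPKM in at least 4 pools the salicylate list gave 0.134 and the clock list 0.0516, and with fry the salicylate list had an adjusted p of 0.132. MicroRNA targets also passed with a pseudocount of 5 (0.0368), with no filter on low values (0.0185) and with fry (adjusted p = 0.00102). Gibberellin genes passed with fry (adjusted p = 0.00317). Median, mean and direction of the limma camera test differed in sign for ABA biosynthesis genes (-0.00012 and -0.0099; test upward), ABA catabolism genes (0.03 and -0.12; test upward), chlorophyll breakdown and leaf senescence (0.0017 and 0.01; test downward) and clade A PP2C genes (0.0021 and -0.02; test upward), the numbers being the median and the mean. Clock genes had 0 rising and 8 falling slopes of 25, 0 and 8 adjusted over the list alone (median -0.05; camera adjusted p = 0.0241, adjusted p = 0.441 with an estimated correlation). CCA1 lay between 27.8 and 42.3 FPKM and TOC1 between 17.7 and 32.2 FPKM over the mock pools. The mock values enter both this series and every ABA effect, so the same values lie behind both.

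Calls at neighbouring times overlapped. Of the tested genes called higher at 3 h in the authors' deposited table, 3761 of 4961 were also called higher at 6 h, where independent lists of those sizes would share 1100.2. Of those called lower, 3240 of 4021 were shared in the authors' deposited table, against 861. Between 0.5 and 24 h, 1073 of 2049 genes called higher at 0.5 h were shared in the authors' deposited table (393 if independent), and 1020 of 2254 called lower (422 if independent). Across genes, which are not independent replicates, the effects correlated with Pearson's r of 0.923 between 3 and 6 h and 0.472 between 0.5 and 24 h. According to the authors' deposited table, 46 genes were called higher at 0.5 and 1 h and lower at 9, 12 and 24 h, and 10 the reverse. A total of 1492 genes were called in both directions at different times in the authors' deposited table.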

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

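Among the tests reported here, the removal of the length trend and the tests of the small RNA genes in the 24 h ABA pool, of fragments in the lower pool and of the clock genes were chosen only after the result was seen.

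Each of 45 measures was compared over 7 times, and in 6 of them the most extreme time stood apart from the rest, where chance would give 2.25 (about 1 in 20). The measures are not independent, since several of the 6 come from the same 1 h or 24 h pools. The 2 counts therefore do not show an excess over chance. The ABA pool of 1 h had the coarsest step between low values, 28.9 FPKM times bases per fragment, which implies 34600000 fragments. The smallest absolute log2 ratio called at 1 h in the authors' deposited table was 0.243, against 0.366 to 0.369 at the other times, and the cause was not tested. The 24 h ABA pool had a Spearman's rho of 0.127 with transcript length relative to the other ABA pools, the 24 h mock pool one of -0.395 relative to the other mock pools and the 24 h effect one of 0.333, all across genes. Auxin response genes had a median effect of 0.54 at 3 h, and the small RNA machinery one of 0.33 at 24 h.

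Late and early effects differed for 2875 genes in limma. Among lists that passed limma's camera and whose early and late medians lay on opposite sides of 0, the late minus early median was -2.18 for salicylate defence, -1.46 for touch and early stress, -1.11 for jasmonate response, 0.70 for heat shock and 0.13 for microRNA targets. None of these calls held with an estimated correlation.

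The small RNA machinery was higher under ABA at 24 h and long-transcript genes were too. With the length trend removed, the median of the 22 genes went from 0.33 (SD 0.38 over genes) to -0.0820 (SD 0.28) and the members above 0 from 14 to 9, so the rise may be a part of the length trend. Among random lists matched on abundance the 24 h median stood at percentile 98.9, and among lists matched on length as well at 83.7. In the 24 h ABA pool the list lay 0.20 above the other ABA pools (SD 0.14; 21 of 22 genes above), and in the 24 h mock pool its departure was -0.15. Since each 24 h group is a single pool, an ABA response in the treated seedlings and a shift of the pools cannot be told apart.

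Large differences without a call, such as PYL6 at 6, 9 and 12 h, went with few fragments in the lower pool. Over all times, of genes with at least 100 implied fragments in the higher pool and 1 to 5 in the lower, 7 of 228 (3.07%) were called in the authors' deposited table, against 78.6% with 6 to 20, 98.7% with over 20 and 82.8% where the lower pool was listed at 0. Low abundance in the higher pool is argued against, since 0 of 39 were called even with at least 1000 fragments there (0%). A rule on few fragments in the lower pool, kept open by its unstated details, may lie behind these missing calls. No biological explanation was tested.

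Clock genes ranged over the mock pools about as far as other genes, with a median range of 0.70 on the log2 scale over 25 genes and 5 ranging over at least 1, at percentile 65.5 of random lists of like abundance. The difference between morning genes (CCA1, LHY) and evening genes (TOC1, PRR5, GI, ELF4, LUX) swung by 0.85 over the mock pools and 1.54 over the ABA pools, as it may if all pools were collected near a single clock phase or from seedlings without a strong rhythm, which the swing does not separate. Compression of all values was not decided, with 3.82% of genes ranging over 2 or more. Light conditions were not given in the sources used here.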

How the results depend on the processing

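The tests with a time left out, with the length trend removed and with all 2-fold differences counted were chosen after the result was seen.

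Genes called in the authors' deposited table and at least 2-fold apart, followed by genes at least 2-fold apart whatever the call, numbered 1016 and 1186 at 0.5 h, 1649 and 1860 at 1 h, 3306 and 3617 at 3 h, 2958 and 3288 at 6 h, 2334 and 2639 at 9 h, 2394 and 2720 at 12 h and 2145 and 2439 at 24 h. With the length trend removed, 2162 of the 19928 genes with a length were at least 2-fold apart at 24 h whatever the call, 1240 higher and 922 lower, against 1210 higher and 1174 lower of the same genes before. All these counts are smaller than the called ones because a 2-fold difference was required. In limma, 1877 genes of the averaged effect and 1493 of late minus early were also at least 2-fold apart. The averaged count stayed within 1.5 times 9417 under the other alternatives, and with a time left out it lay between 7092 and 9388.

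With a time left out, late minus early gave 1249 (without 0.5 h) to 2653 genes (without 24 h), the effect by time 82 (without 1 h) to 1409 (without 24 h), and the mock time course 2201 (without 1 h) to 8474 (without 24 h). With no filter on low values the effect by time gave 490 genes. Apart from fewer times and more genes tested, the cause was not tested. The 15, 11 and 9 lists past the threshold in camera for the averaged effect, late minus early and the mock time course became 0, 0 and 0 with an estimated correlation, 17, 8 and 10 with fry, and for late minus early 7 (without 24 h) to 12 (without 1 h) with a time left out.

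No named gene or list past the threshold reversed its direction under the alternatives run. Over these, named genes kept their side of the threshold in 2192 comparisons, lost a call in 73 and gained one in 2. Of 190 named values, 168 never changed side. Lists kept their side in 1056 comparisons, lost a call in 63 and gained one in 15. Direction was compared only for results past the threshold. Below it, the late minus early direction of clade A PP2C and osmolyte genes was upward with camera and downward with fry. Quantile normalization changed the averaged split from 4779 higher and 4638 lower to 4191 and 5502, with a shift of the median gene to -0.05.

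No paired analysis was possible because the columns of the table carry no replicates. For the same reason fits of the 4 libraries of a time or of the 14 mock libraries, leaving out single libraries, and tests on counts were not run, and pseudocounts or normalization cannot alter the authors' calls. Calls were few where the lower pool held 1 to 5 fragments of a gene, for a reason left open. The limma fits recovered 46% of simulated late minus early differences of 1 on the log2 scale. The simulated noise was smaller than the measured spread over the mock pools, so this share may be too high.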

Other observations

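Of the tests in this part, those with a time left out were chosen after the result was seen, and the microRNA loci were picked for their values.

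Genes called higher at all 7 times in the authors' deposited table carried ABA-responsive elements near their start more often than other tested genes. The element (ACGTG, then G or T, then C, on either strand) lay in the 500 bases upstream of 193 of 698 such genes (27.7%) and of 9.73% of 18797 others, a ratio of 2.84 (Fisher's exact test, two-sided, p = 4.27e-39). A control word with 1 base changed was found in 9.17% and 4.45%, so part of the excess is shared with related words. The share with the element was 6.39% for genes called lower at all 7 times in the authors' deposited table, 20.98% for genes called higher at 0.5 h, 11.3% for those first called higher at 3 h and 10.8% for those first called at 9 h or later. Genes called higher at all 7 times are also among those called higher at 0.5 h, so these shares do not separate a lasting rise from an early one. A tie to direct binding of ABF-type factors is a hypothesis that binding data would have to test.

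Chance in which pool was ABA is argued against for the averaged effect, since 1 of 64 arrangements reached 9417 genes in limma. The arrangements exchanged ABA and mock within times, that 1 was the real one, and the highest of the others gave 3578. A share of 1 in 64 is the smallest that this test can give, so chance is not excluded beyond that limit.

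Of 178 microRNA loci in the table, 30 reached 1 FPKM in some pool, and 10 were called at some time, 2 of them higher at all 7 times, in the authors' deposited table. These reads come from the loci's longer transcripts and do not measure mature microRNAs. Of 18 loci tested with limma on the averaged effect, 6 passed higher and 1 lower under ABA. Over all times MIR408 averaged 2.03, MIR824 1.84, MIR398c 1.09, MIR167d 0.74 and MIR163 -1.44, all among those that passed. Among targets of the miR398 family, CSD2 averaged -1.38 and CSD1 -0.83, the last with a call lost without 9 h (-0.72) or 12 h (-0.71). Over all microRNA targets, however, 23 of 73 tested genes passed higher and 13 lower, LAC12 and NFYA5 among the higher. Whether targets move against their microRNA loci was not tested.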
